A study of Homo sapiens with 6 samples.

How the data were processed

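The 6 samples were total RNA from vastus lateralis muscle, 3 taken at baseline and 3 after supplementation, biotin labelled with a whole-transcript terminal labelling kit, per the labels' protocols. The authors deposited 1 table of RMA values on the log2 scale, per the submitters' processing notes, which name RMA (robust multi-array average), a method that corrects background, normalizes arrays by quantiles and summarizes probes. Its version and settings are not given in the sources used here. The table holds 70523 features for each array, of which 67528 are transcript cluster probe sets and 2995 are control or other probe sets. Whether all 6 arrays were normalized together is not stated, and every comparison between arrays rests on it. Array medians ran from 2.41 to 2.64 and lower quartiles from 1.39 to 1.60. Quantile normalization brings array distributions close, so a change in total RNA per sample cannot be seen in these log2 values. No genome build is given in the sources used here, and no coordinates are printed.

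Probe sets were named through the platform's annotation table. A single gene symbol was given for 23781 probe sets, several for 1543 and none for 45199 features. Probe sets with several symbols were named for no gene. Symbols were updated through gene identifiers and synonyms of the RefSeq annotation of GRCh38.p14, used for names only, and 306 changed. Y-linked genes and XIST were left out of every step. For the 504 genes with more than 1 probe set the one with the highest mean over the 6 arrays was used, which gave 22348 genes, and genes under the 0.25 quantile of mean signal (2.21 log2 units) were left out, which left 16761.

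Supplemented and baseline arrays were compared with limma 3.58.1 in R 4.3.3, by lmFit and eBayes on the log2 values, with the subject as a block, since the series design states that the same 3 subjects were sampled both times and the labels give the subject of each array. Two-sided p values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The fit had 2 residual degrees of freedom and a prior worth 4.47. As a check of the pairing, the 2 arrays of a subject had deviations from their group means that correlated at 0.643, 0.549 and 0.417 across genes. Arrays of different subjects in the 2 groups correlated at 0.493 and 0.426 between the pairs with high muscle transcripts and from -0.613 to -0.497 with the third, so the correlations separate 1 pair from the others but not those others from each other, and the pairing rests on the labels. Intervals are 95% intervals from limma, and SE is the moderated standard error of the change. The limma p values measure the spread between these 3 subjects, with the variance of each gene drawn towards that prior, which is taken over all genes.

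The 32 gene lists, the rule for named genes, the design and the alternatives were fixed before the data were examined. Lists were tested with camera on the same fit, with a preset correlation of 0.01 between genes, and repeated with an estimated correlation and with fry, which tests whether the genes of a list move, on balance, one way and does not compare the list with other genes. Camera p values with the preset correlation rest on the spread between genes, not on that between subjects. With an estimated correlation camera takes its p values from the 2 residual degrees of freedom of the fit. They are then larger even where the estimate is under 0.01. Adjustment was over the 32 lists. The rule named the 12 genes that rose and the 12 that fell with the smallest p among genes with the same sign in all 3 pairs, taking those with an adjusted p under 0.05 first and then the next by p with at least a 1.5-fold change. It also named the 2 members with the smallest p of each list, up to 4 where the list passed camera, all 6 genes of a list recalled from the published study of these samples, which was not checked against that study here, and up to 4 abundant members of a cell type list that moved.

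The limma fit and camera were tested on simulated arrays for 16761 genes. Variances were drawn from the prior that limma fitted to these data, and the noise was independent between genes. With no change 0 genes were called. With 200 genes changed 2-fold limma recovered 49.5% of them with 6 other calls, and with 200 changed 4-fold it recovered 99% with 12 other calls. With the collagens raised, camera called that list and no other of the 32. Since the simulated genes varied independently, this does not test camera's preset correlation on lists whose genes move together.

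Alternatives were no block, no filter or a filter at the median signal, quantile, median or cyclic loess scaling on top of the deposited values, a prior with an intensity trend and robust estimation, array weights, the mean of a gene's probe sets or each probe set on its own, a plain paired test, and leaving out each subject in turn. Where lists were tested in these alternatives, camera kept its preset correlation, and the fits without a subject rest on the remaining subjects alone. Transcript clusters with several symbols or none were tested in a separate limma fit. Random gene sets for the closing tests were matched to a list in size and in 10 bins of mean signal, with 10000 draws. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.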

Results

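Gene expression was measured in the vastus lateralis, a thigh muscle, of 3 subjects before and after 8 weeks of supplementation with PrimaVie Shilajit at 250 mg taken 2 times a day. Shilajit is a mineral-rich exudate of mountain rocks, and PrimaVie is a purified preparation of it. Each of the 6 samples was run on its own Affymetrix whole-transcript array, giving 3 baseline and 3 supplemented arrays that form 3 pairs from the same subjects. The array medians ran from 2.41 to 2.64 on the log2 scale. The number of arrays limits the precision of every value. After naming and the filter on dim probe sets, 16761 genes were tested for the question the design asks, which is how muscle transcripts differ after supplementation from before it. All samples taken after baseline came from supplemented subjects, so that time, repeated sampling and the supplement cannot be separated here.

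Transcripts of the extracellular matrix and of the cells that make it were higher after supplementation. In total 17 genes rose and 0 fell at an adjusted p under 0.05 in limma with the subject as a block, with folds from 2.44 to 7.19 and the same sign in all 3 pairs for each of the 17. Among these 17 the largest rise was that of FNDC1, a fibronectin type III domain protein (transcript cluster TC06001142.hg.1), from 3.84 ± 0.55 to 6.69 ± 0.56 log2 units (SD, n = 3), which is 7.19-fold with a 95% interval of 5.83 to 8.87 (limma adjusted p = 0.00352). Both chains of type I collagen, the main fibrillar collagen, rose: COL1A2 by 2.77 ± 0.24 log2 units (SE, n = 3 pairs) and COL1A1 by 2.46 ± 0.22. COL6A3 of the microfibrillar type VI collagen rose by 1.94 ± 0.16 and COL14A1 by 1.82 ± 0.15. FN1, which encodes fibronectin (TC02002747.hg.1), rose by 2.21 ± 0.15, from 5.86 ± 0.88 to 8.07 ± 0.65 log2 units (SD, n = 3).

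Among the small leucine-rich proteoglycans, which bind collagen fibrils, LUM rose by 1.99 ± 0.13, ASPN by 1.91 ± 0.18 and OGN by 1.82 ± 0.15 log2 units (SE, n = 3 pairs). LUM was dim at baseline, with a mean of 2.22 beside the filter value of 2.21, so the size of its rise is uncertain. POSTN, a matricellular protein, rose by 1.72 ± 0.18. The matrix metalloproteinase genes MMP2 and MMP14, whose product activates the MMP2 protein, rose by 2.36 ± 0.20 and 1.29 ± 0.12. The secreted Wnt modulators SFRP4 and SFRP2 rose by 2.45 ± 0.21 and 1.87 ± 0.13. CYBB, a subunit of the phagocyte NADPH oxidase, rose by 1.72 ± 0.15, HMCN1, a large matrix protein, by 1.60 ± 0.14 and CCDC80 by 1.79 ± 0.17. Of the 17 genes, 11 were in a list of matrix genes, 2 in the fibroblast list and 4 in no list, and the largest of their limma adjusted p values was 0.0426. CCDC80 and POSTN lie outside the rule for named genes and were named after their values were seen.

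**Figure D1:**
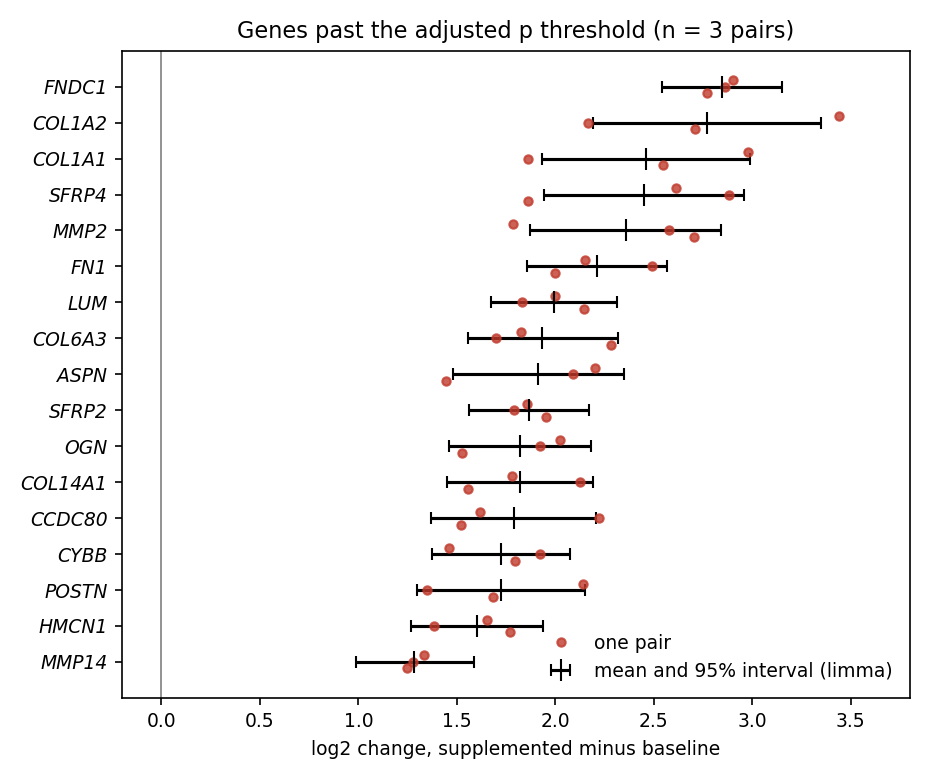
Change of each of the 17 genes past the threshold, on the log2 scale (supplemented minus baseline); points are single pairs, and the bar is the limma mean with its 95% interval. All points lie above 0, from FNDC1 with a mean of 2.85 down to MMP14 with 1.29.

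The count of 17 genes rested on the fit with the subject as a block. Without the block limma called 0 genes, with 586 at an unadjusted p under 0.05 against 1292 with it, and a plain paired test of each gene also called 0. Without the pair whose arrays held low muscle transcripts, described with the fibre genes, limma called 0 genes as well. At an unadjusted p under 0.05 it then had 1666 genes (915 higher, 751 lower), among them all 17. Each was still higher, which its rise in every pair had fixed in advance. Leaving out each of the other pairs in turn gave 143 genes (128 higher, 15 lower) and 320 genes (286 higher, 34 lower). Scaling the arrays again gave 5 genes by quantiles, 6 by medians and 8 by cyclic loess, all among the 17. At an unadjusted p under 0.05, 938 genes were higher and 354 lower, where chance gives 838 in all.

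The fixed lists of matrix genes moved together, and each had a higher mean in all 3 pairs. Among glycoproteins and proteoglycans 5 of 24 genes rose, and 19 adjusted over the list alone, with a mean change of 1.02 ± 0.22 log2 units (SD over 3 pairs; camera adjusted p = 1.16e-29). Among collagens 4 of 19 rose, and 11 adjusted over the list alone, with a mean of 0.76 ± 0.06 (camera adjusted p = 2.28e-14). Of 29 genes of matrix processing, which cover collagen folding, cross-linking and breakdown, 2 rose, and 5 adjusted over the list alone, with a mean of 0.37 ± 0.06 (camera adjusted p = 1.87e-08). CTSK, the collagen-degrading cathepsin K, was 1.75 ± 0.19 higher (SE) and missed the threshold (limma adjusted p = 0.0568), and ADAMTS2, which trims procollagen, was 0.64 ± 0.13 higher. With an estimated correlation these 3 lists missed the threshold (camera adjusted p = 0.278 with an estimated correlation for each). The estimate was 0.177 for glycoproteins and proteoglycans, but -0.0383 for collagens and -0.0331 for matrix processing, both under the preset 0.01. For collagens and matrix processing the loss thus did not come from correlated genes. The collagens were the 1 list of 32 that passed fry (adjusted p = 0.0481).

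No gene of the elastic fibre and basement membrane lists passed over all genes, although both lists had a higher mean. Of 18 elastic fibre genes 0 rose, and 12 adjusted over the list alone, with a mean of 0.63 ± 0.28 log2 units (SD over 3 pairs; camera adjusted p = 1.36e-13, and adjusted p = 0.377 with an estimated correlation). FBN1, which encodes fibrillin 1, was 1.92 ± 0.29 higher (SE), MFAP4 1.03 ± 0.19, LTBP1 0.91 ± 0.13 and the cross-linking enzyme LOX 0.81 ± 0.14. Of 11 basement membrane genes 0 rose, and 10 adjusted over the list alone, with a mean of 0.59 ± 0.16 (camera adjusted p = 1.59e-11, and adjusted p = 0.278 with an estimated correlation). LAMA4, a laminin chain, was 1.14 ± 0.13 higher (limma adjusted p = 0.0668), and the nidogens NID1 and NID2, which link laminin to collagen IV, were 0.82 ± 0.15 and 0.67 ± 0.14 higher. LAMB1 was 0.79 ± 0.15 higher.

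A further list held 6 genes recalled as named in the published study of these samples, which was not checked against that study here. All 6 were higher in each pair, with a mean change of 1.36 ± 0.40 log2 units (SD over 3 pairs; camera adjusted p = 1.83e-12, and adjusted p = 0.278 with an estimated correlation). If recalled rightly, this list was chosen on these samples, and it is not independent evidence of its direction. Over all genes 1 of the 6 rose, FN1, and 6 did so adjusted over the list alone. The others were FBN1, DCN at 1.40 ± 0.20 (SE), TNXB at 1.11 ± 0.25, MYOF at 1.07 ± 0.17 and ELN at 0.42 ± 0.13, with limma adjusted p values of 0.128, 0.118, 0.273, 0.154 and 0.459 in that order. DCN encodes decorin, ELN elastin and MYOF myoferlin, a membrane protein rather than a matrix one. The TNXB probe set belongs to an alternative haplotype sequence, and TNXB shares near-identical sequence with its pseudogene.

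Markers of fibroblasts and macrophages were higher as well, while those of most other cell types did not pass. Of 16 fibroblast markers outside the matrix lists 2 rose, SFRP2 and SFRP4, and 14 adjusted over the list alone, with a mean change of 0.85 ± 0.21 log2 units (SD over 3 pairs; camera adjusted p = 9.03e-17, and adjusted p = 0.278 with an estimated correlation). DPP4 was 1.42 ± 0.18 higher (SE) and the complement protease gene C1S 0.95 ± 0.13. Of 17 macrophage and monocyte markers 0 rose, and 11 adjusted over the list alone, with a mean of 0.69 ± 0.27 (camera adjusted p = 1.36e-13, and adjusted p = 0.351 with an estimated correlation). LYVE1 was 1.39 ± 0.27 higher, the clotting factor gene F13A1 1.19 ± 0.20, the mannose receptor gene MRC1 1.13 ± 0.22 and FCER1G 1.08 ± 0.16. Endothelial markers had a mean change of 0.10 ± 0.10 (camera adjusted p = 0.0616, and 0.0169 with no filter on mean signal), with PECAM1 0.41 ± 0.13 and KDR 0.42 ± 0.14 higher.

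Of 14 pericyte and smooth muscle markers 0 rose, and 1 adjusted over the list alone, PDGFRB at 1.05 ± 0.20 log2 units (SE). The list mean was 0.34 ± 0.35 (SD over 3 pairs; camera adjusted p = 0.00223, and adjusted p = 0.421 with an estimated correlation), and without the pair with the largest change it was 0.14 and did not pass (camera adjusted p = 0.118). MYH11 was at 1.18 ± 0.44, ABCC9 0.57 ± 0.22 and MCAM 0.32 ± 0.18. Of 14 adipocyte markers 0 rose, and 1 adjusted over the list alone, the lipogenic gene THRSP at 1.35 ± 0.20. The adipocyte mean was 0.23 ± 0.20 (camera adjusted p = 0.00701, and adjusted p = 0.53 with an estimated correlation), and it did not pass without the block, after quantile or cyclic loess scaling, or without 1 of the other pairs (0.12, camera adjusted p = 0.167). ADIPOQ was at 0.62 ± 0.20, FABP4 at 0.36 ± 0.14 and PLIN4 at 0.23 ± 0.15. Skin epithelium markers, which include keratins, had a mean of -0.18 ± 0.18 (camera adjusted p = 0.0288, and adjusted p = 0.74 with an estimated correlation). The list did not pass without the pair with low muscle transcripts (described with the fibre genes) at -0.11 (camera adjusted p = 0.0944), without another pair, at -0.16 (camera adjusted p = 0.331), or after quantile or cyclic loess scaling, and without the third it was at -0.28 (camera adjusted p = 0.0244). Its members SFN, KRT2, KRT14 and PKP1 had changes of -0.42 ± 0.17, -0.22 ± 0.13, -0.20 ± 0.16 and -0.18 ± 0.13.

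The remaining cell type lists did not pass in camera with all 3 pairs. The nerve and Schwann cell list had a mean change of -0.18 ± 0.27 log2 units (SD over 3 pairs; camera adjusted p = 0.0666), with MAL at -0.30 ± 0.18 (SE) and SOX10 at -0.38 ± 0.23, and it passed without 1 pair, at -0.28 (camera adjusted p = 0.0463). The tendon list, which shares members with the matrix lists, had a mean of 0.11 ± 0.26 (camera adjusted p = 0.832). Its members FMOD at 0.65 ± 0.17 and TNC at 0.68 ± 0.20 were the 2 that passed adjusted over the list alone, and 0 passed over all genes. The lymphocyte list had a mean of -0.03 ± 0.20 (camera adjusted p = 0.849), with CD4, which monocytes also express, at 0.47 ± 0.16 and CD79B at -0.18 ± 0.15. The neutrophil list had a mean of 0.02 ± 0.03 (camera adjusted p = 0.832), with MNDA at 0.31 ± 0.18 and MPO at -0.19 ± 0.13. The erythrocyte list had 4 tested genes and a mean of 0.01 ± 0.48 (camera adjusted p = 0.832), with ALAS2 and SLC4A1 both at -0.13 ± 0.14.

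**Figure D2:**
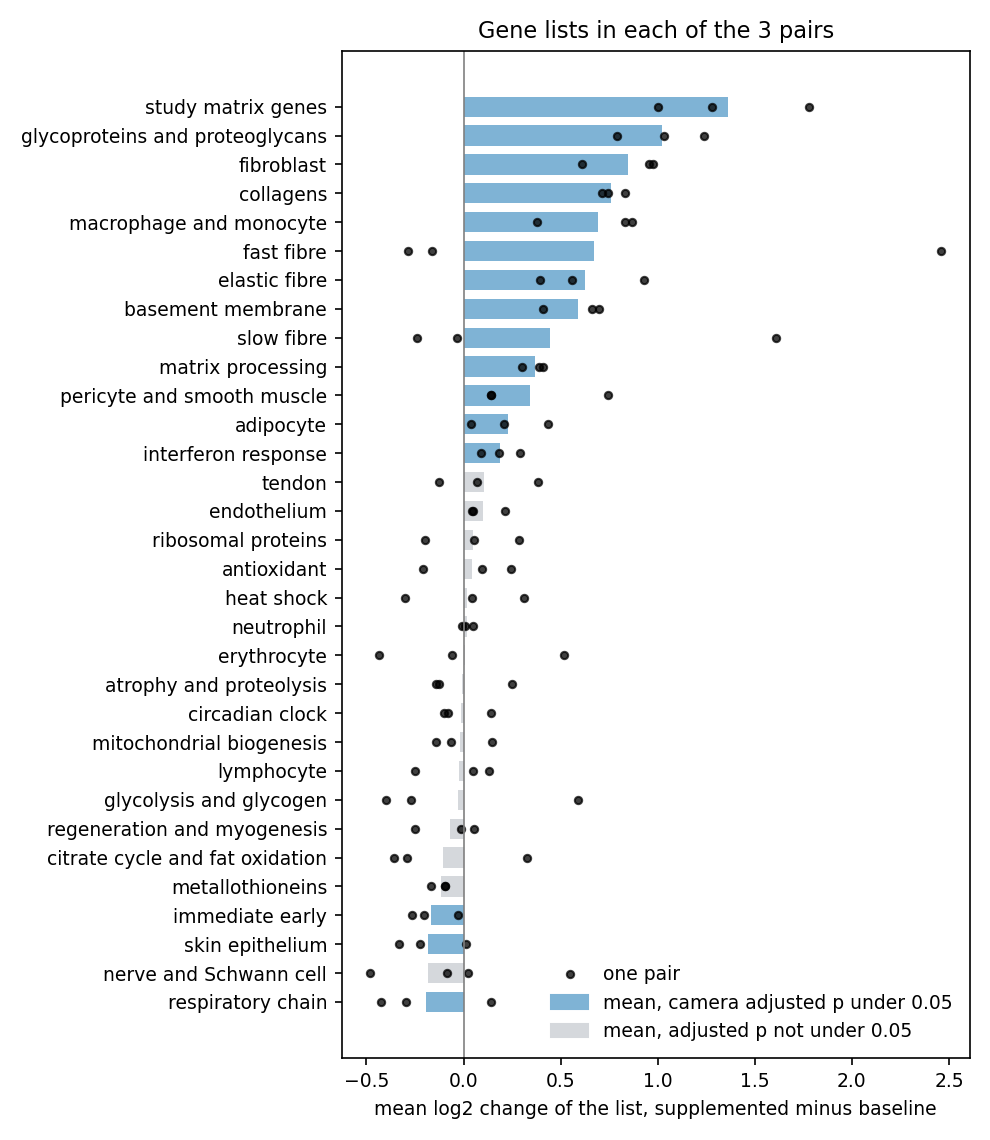
Mean log2 change (supplemented minus baseline) of each of the 32 gene lists; bars are means over 3 pairs, coloured by whether the camera adjusted p with its preset correlation is under 0.05, and points are single pairs. The matrix, fibroblast and macrophage lists lie above 0 in every pair, while the fast and slow fibre lists lie above 0 in 1 pair, at 2.46 and 1.61, and below 0 in the others.

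Muscle fibre transcripts differed more between pairs than between time points. In both arrays of 1 pair they were low: the fast and slow fibre genes averaged 4.62 log2 units at baseline and 6.72 after supplementation, against 8.53 to 8.84 in the other 4 arrays. MYH2, the fast type IIA myosin heavy chain, was at 4.55 and 9.11 in that pair, and MYH7, the slow myosin heavy chain, at 5.63 and 8.52, with at least 10.9 and 10.6 in the others. The same 2 arrays held more adipocyte transcripts, at a list mean of 7.19 and 7.39 against 5.25 to 5.69, and FABP4 was at 9.19 and 9.45 against 5.92 to 6.65. The baseline array of that pair also had the highest median of the background probe sets, 1.99 against 1.40 to 1.56 on the other 5, and the lowest labelling controls, 3.13 against 5.02 to 5.84. A principal component holding 64.2% of the variance set this pair apart from the other 4 arrays.

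The rise of the fibre lists in camera came from that pair. The fast fibre list had a mean change of 0.67 ± 1.55 log2 units (SD over 3 pairs; camera adjusted p = 0.00701, and adjusted p = 0.808 with an estimated correlation), which was 2.46 in that pair and -0.16 and -0.29 in the others. The slow fibre list had 0.44 ± 1.01 (camera adjusted p = 0.0134, and adjusted p = 0.74 with an estimated correlation), which was 1.61, -0.24 and -0.03. Of 15 fast and 11 slow fibre genes 0 passed over all genes and 0 adjusted over the list alone. MYH1, MYL1, MYH2 and MYL11 had changes of 2.19 ± 0.94 (SE), 1.31 ± 0.79, 1.38 ± 0.89 and 1.02 ± 0.78. MYH7, ATP2A2, MYL2 and TNNC1 had changes of 0.96 ± 0.55, 0.57 ± 0.35, 0.81 ± 0.55 and 0.70 ± 0.53. Without that pair the fast and slow fibre lists turned, to -0.22 and -0.14 (camera adjusted p = 4.21e-05 and 0.0127), without either other pair they were at 1.09 or 1.15 and at 0.79 or 0.68, with array weights at -0.04 and -0.09, and neither list passed without the block or with cyclic loess. These refits kept the preset correlation of 0.01. With all 3 pairs the estimated correlation was 0.935 in the fast and 0.708 in the slow fibre list.

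**Figure D3:**
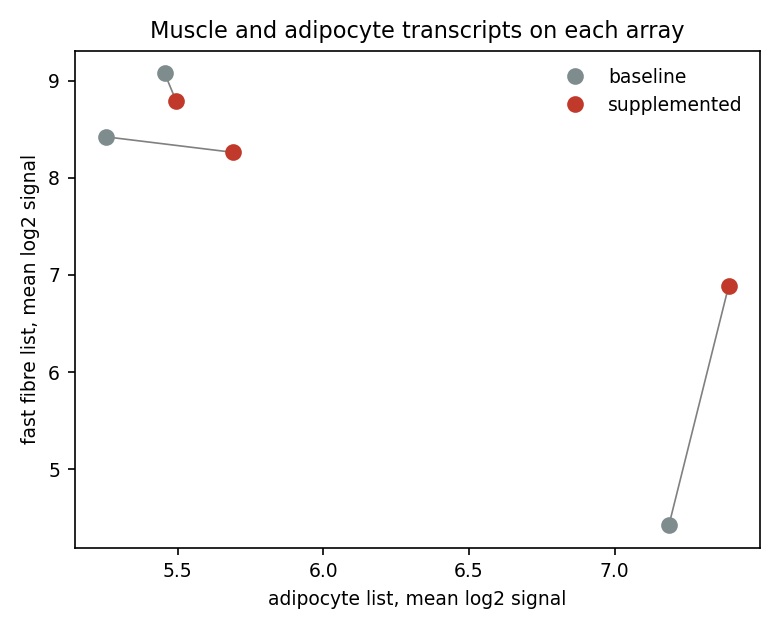
Mean log2 signal of the adipocyte list (x axis) and of the fast fibre list (y axis) on each of the 6 arrays, with a line joining the arrays of 1 subject. Both arrays of 1 pair lie apart, with fast fibre means of 4.43 and 6.88 against 8.26 to 9.08 on the others.

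Genes of energy metabolism did not pass one by one. The respiratory chain list fell in camera, with a mean change of -0.19 ± 0.30 log2 units (SD over 3 pairs; camera adjusted p = 2.87e-06, and adjusted p = 0.74 with an estimated correlation). Its mean was 0.14 in the pair with low muscle transcripts and -0.30 and -0.43 in the others, and of 49 genes 0 passed over all genes and 0 adjusted over the list alone. Without the pair with low muscle transcripts it was at -0.36 (camera adjusted p = 1.88e-22), and without either of those others it did not pass, at -0.14 and -0.08 (camera adjusted p = 0.055 and 0.179). NDUFA2, NDUFB10, ATP5MG and ATP5ME had changes of -0.45 ± 0.14 (SE), -0.42 ± 0.15, -0.41 ± 0.15 and -0.39 ± 0.13. The citrate cycle and fat oxidation list had a mean of -0.11 ± 0.38 (camera adjusted p = 0.113), with CPT1B, which admits fatty acids to mitochondria, at -0.25 ± 0.12 and HADH at -0.24 ± 0.16. The glycolysis and glycogen list had -0.03 ± 0.54 (camera adjusted p = 0.832), with ALDOA at -0.29 ± 0.13 and the insulin-responsive glucose transporter gene SLC2A4 at -0.28 ± 0.16. The mitochondrial biogenesis list had -0.02 ± 0.15 (camera adjusted p = 0.832), with PPARGC1A at -0.33 ± 0.19 and DNM1L at 0.28 ± 0.19. Without the pair with low muscle transcripts these 3 lists passed, at -0.33, -0.34 and -0.10 (camera adjusted p = 3.18e-12, 5.01e-08 and 0.031), as they did with array weights, at -0.31, -0.32 and -0.11 (camera adjusted p = 9.83e-09, 4.27e-05 and 0.0279), and without another pair the glycolysis list passed in the other direction, at 0.16 (camera adjusted p = 0.0209). The citrate cycle and fat oxidation list also passed after quantile scaling, at -0.15 (camera adjusted p = 0.00655), and cyclic loess, at -0.14 (camera adjusted p = 0.0016). These refits kept the preset correlation of 0.01 and were not repeated with an estimated one. With all 3 pairs the estimate was 0.599 for the respiratory chain and 0.476 for the citrate cycle list. It was 0.542 for the glycolysis and 0.0882 for the mitochondrial biogenesis list.

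The lists of muscle remodelling, clock and ribosomal protein genes did not pass with all 3 pairs weighted alike. The regeneration and myogenesis list had a mean change of -0.07 ± 0.16 log2 units (SD over 3 pairs; camera adjusted p = 0.87), with the perinatal myosin gene MYH8 at 0.45 ± 0.16 (SE) and MYOD1 at -0.68 ± 0.26. The atrophy and proteolysis list had -0.01 ± 0.22 (camera adjusted p = 0.832), with the cathepsin gene CTSL at 0.51 ± 0.21 and BNIP3 at -0.31 ± 0.15. The circadian clock list had -0.01 ± 0.13 (camera adjusted p = 0.939), with PER3 at 0.30 ± 0.17 and TEF at -0.25 ± 0.15. The ribosomal protein list had 0.05 ± 0.24 (camera adjusted p = 0.228), with RPS28 at 0.30 ± 0.13 and RPL30 at -0.23 ± 0.12. Without the pair with low muscle transcripts the atrophy list passed, at -0.13 (camera adjusted p = 0.0127), as it did with array weights, at -0.12 (camera adjusted p = 0.0369), and without another pair the ribosomal list passed, at 0.17 (camera adjusted p = 0.0161).

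Among stress lists the interferon response rose and the immediate early genes fell in camera, with no single gene past the threshold. The interferon list had a mean change of 0.19 ± 0.10 log2 units (SD over 3 pairs; camera adjusted p = 0.00701, and adjusted p = 0.421 with an estimated correlation), with 0 of 17 genes past the threshold and 0 adjusted over the list alone. IFI6 was at 1.10 ± 0.29 (SE), IFI44 at 0.53 ± 0.13, IFITM1 at 0.48 ± 0.14 and IFI27 at 0.48 ± 0.16. The immediate early list had -0.17 ± 0.12 (camera adjusted p = 0.0183, and adjusted p = 0.377 with an estimated correlation), with 0 of 22 past the threshold and 0 adjusted over the list alone. The immediate early list did not pass without 1 or the other of the pairs with high muscle transcripts, at -0.15 and -0.12 (camera adjusted p = 0.149 and 0.179). NR4A3 was at -0.60 ± 0.20, FOS at -0.44 ± 0.17, NR4A1 at -0.38 ± 0.13 and FOSB at -0.37 ± 0.13. The antioxidant list did not pass, at 0.04 ± 0.23 (camera adjusted p = 0.657), with the ferritin light chain gene FTL at 0.82 ± 0.20 and PRDX2 at -0.27 ± 0.13. Metallothioneins, which bind metals, were at -0.12 ± 0.04 (camera adjusted p = 0.228), with MT1X at -0.49 ± 0.15 and MT1H at -0.26 ± 0.13, and heat shock genes at 0.02 ± 0.31 (camera adjusted p = 0.939), with HSPB7 at -0.58 ± 0.18 and HSPA5 at 0.58 ± 0.20. Without the pair with low muscle transcripts the heat shock list was at -0.13 (camera adjusted p = 0.031).

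No gene was lower at an adjusted p under 0.05 in limma, and the smallest limma adjusted p on that side was 0.177. Other limma fits did call lower genes, 67 with array weights and 15 and 34 without 1 or the other of the pairs with high muscle transcripts. The 12 genes lower in all 3 pairs with the smallest p and at least a 1.5-fold change did not pass. KIFC1, a mitotic kinesin gene whose probe set belongs to an alternative haplotype sequence, led them at -1.03 ± 0.17 log2 units (SE, n = 3 pairs). KLHL34 was at -0.995 ± 0.248, TMT1B at -0.92 ± 0.17, TENT5B at -0.78 ± 0.16 and NMRK2, a nicotinamide riboside kinase gene of muscle, at -0.69 ± 0.18. The other 7 were short or non-coding transcripts. SNORD115-32 was at -0.89 ± 0.20, RNA5SP113 at -0.84 ± 0.15, LINC00602 at -0.79 ± 0.14, VIPR1-AS1 at -0.78 ± 0.17, RNA5SP497 at -0.71 ± 0.14, MIR4635 at -0.65 ± 0.16 and MIR3132 at -0.59 ± 0.13. SNORD115-32 and VIPR1-AS1 were dim, with supplemented means of 1.85 and 2.15, under the filter value of 2.21. For KIFC1, TMT1B, LINC00602, RNA5SP113, RNA5SP497 and VIPR1-AS1 the fall was largest in the pair with low muscle transcripts, and for the others in another pair.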

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

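All tests of explanations in this part were chosen after the results were seen. Transcript clusters with no gene symbol or with several, which no comparison used, also changed: of 19339 tested in limma, 5 were higher and 0 lower at an adjusted p under 0.05, and 1117 had an unadjusted p under 0.05. Of the 5, 4 have no symbol and 1, TC02001105.hg.1, carries both COL3A1 and MIR3606 and is named for no gene. It was 2.89 ± 0.23 log2 units higher (SE), and COL3A1, a member of the fixed collagen list, was not among the 19 tested genes of that list. The 5 were higher by 2.30 to 3.03 log2 units, led by p in TC02003743.hg.1 at 2.65 ± 0.21 (SE, n = 3 pairs, limma adjusted p = 0.0264).

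Matrix, fibroblast and macrophage genes were higher after supplementation. A lower share of muscle fibres with the other cell types in their old proportions would have raised endothelial markers as much as fibroblast markers. The fibroblast change exceeded the endothelial one by 0.744 ± 0.182 log2 units (SD over 3 pairs), in every pair. The fibroblast list was singled out in the pattern for its rise, which favours such a gap. Endothelial markers, which are outside the pattern, changed by 0.102 ± 0.0973 and showed no rise of that size. Other lists outside the pattern differed from them: pericyte and smooth muscle markers were at 0.344 ± 0.346 and adipocyte markers at 0.228 ± 0.2, both higher in every pair. Lymphocyte, nerve and Schwann cell, and skin epithelium markers were at -0.0254 ± 0.2, -0.181 ± 0.265 and -0.181 ± 0.178. The comparison thus holds for endothelial markers only. The pair with low muscle transcripts was not the only source, since the 5 fixed matrix lists were also higher by 0.781 and 0.545 in the other pairs. These values lay above the upper ends of the central 95% of random gene sets, 0.154 and -0.00498. Genes of a random set need not move together, so a list whose genes do can pass these ends more easily. Without the pair with low muscle transcripts limma called 0 genes. More fibroblasts or connective tissue in the second samples stays open: fibroblast markers outside the matrix lists were higher by at least 0.61 in each pair, above the upper end for random sets in all 3, but they are part of the pattern and decide nothing. Higher transcription per cell was not tested, and supplementation, elapsed time, the place of sampling and the earlier sampling of the muscle stay open, because no second sample without supplement was analysed here.

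In 1 pair both arrays held low muscle and high adipocyte transcripts. The adipocyte list was higher in each of its arrays than in the other 4 by at least 1.5 log2 units, and LEP, an adipocyte hormone gene, was at 8.03 and 8.55 against at most 4.36. These values are part of the pattern, so adipose tissue in place of muscle stays open and was not tested apart from them. The labelling controls of its supplemented array were 0.253 log2 units above the highest of the other 4, which argues against weak labelling there. Weak labelling may add to the lower muscle transcripts of its baseline array, whose labelling controls were at -1.89 log2 units relative to the lowest of the other 4. The ribosomal protein list of that array was not low, at 5.77 against 5.65 to 6.02 on the other 4, and the part of weak labelling was not tested further. No biological explanation was tested, since the design names no group that sets this pair apart.

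The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. With the subject as a block, the 6 splits that part only 1 pair fall into couples with the same contrast and the same counts. The 10 are therefore not all distinct, and the shares below count some contrasts more than once. For genes past the threshold the real split gave 17 and the highest of the others 20, and 3 of the 10 splits gave as many. For genes at an unadjusted p under 0.05 the values were 1292 and 5439, with 3 splits giving as many. The 2 splits behind these highest values part only the pair with low muscle transcripts and are such a couple. Their contrast is the difference between that pair's own arrays and points to a structure of the samples. Among the 4 splits that part every pair, the other 3 gave 0 genes and 332 to 555 at an unadjusted p under 0.05. For gene lists past the threshold the real split gave 16 and the highest of the others 19, with 7 of the 10 splits giving as many, and among those that part every pair the others gave 9 to 19. The number of lists that pass camera with its preset correlation thus does not set the real split apart.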

How the results depend on the processing

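The alternatives were planned before the data were examined. The 17 called genes kept their direction in all 13 settings where they were tested (16 of them in the set at or above the median signal), but their number past the threshold depended on the setting. Each had risen in every pair, so leaving out a pair could not turn its sign, and the kept direction adds no support. Against 17 with the subject as a block, limma called 0 genes without the block (16 of the 17 had an unadjusted p under 0.05), 5 after quantile scaling, 6 with medians centred, 8 after cyclic loess, 26 with an intensity trend and robust prior, 497 with array weights (430 higher, 67 lower) and 0 in the plain paired test, which had 926 at an unadjusted p under 0.05. Leaving out 1 subject gave 0 to 320 genes. Without the pair with low muscle transcripts the count was 0, and without each of the others 143 (128 higher, 15 lower) and 320 (286 higher, 34 lower), each including all 17.

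Genes at an unadjusted p under 0.05 numbered 1292 with the block, 586 without it (319 higher, 267 lower) and 3050 with array weights (1775 higher, 1275 lower), and 990 to 1666 when 1 subject was left out. Gene lists past the threshold numbered 16 with camera's preset correlation, 0 with an estimated correlation, 1 with fry, 13 to 20 with 1 subject left out and 13 without the block. The study matrix genes had a mean change of 1.36, which no longer passed with an estimated correlation (adjusted p = 0.278) or fry (adjusted p = 0.0946), and 1.14 to 1.53 with 1 subject left out.

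The slow and fast fibre lists turned with array weights, to -0.0915 and -0.043, and ran from -0.137 to 0.787 and from -0.224 to 1.15 with 1 subject left out. The glycolysis and glycogen list ran from -0.335 to 0.158, and the heat shock list from -0.128 to 0.178. The lowest value of each of these 4 lists was the one without the pair with low muscle transcripts. The 6 matrix lists and the fibroblast, macrophage and interferon lists kept their call without each subject, without the block and under every scaling. Array weights gave that pair's arrays 0.267 each, which lowers its part in the result, and the cause of the other changes was not tested. Where neither fit passed the threshold, a change of sign was not counted as a turn: 38 of 208 list values and 12 of 1044 gene values had another sign. Besides the 6 list values that turned, 46 list values and 56 gene values lost their call and 13 and 96 gained one, in the same direction. The 46 leave out the study matrix genes, whose 2 losses are given above. In every setting the median change of all genes lay between -0.0573 and 0.00266 log2 units. With 3 pairs, limma recovered 49.5% of simulated 2-fold changes, so smaller changes can be missed.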

Other observations

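The test in this part and its gene groups were chosen after their values were seen. Of 19 genes of fatty acid and triglyceride synthesis 9 were higher and 1 lower in all 3 pairs, and 0 passed in limma over all genes. SCD was 1.37 ± 0.27 log2 units higher (SE, n = 3 pairs), THRSP 1.35 ± 0.20, GPAM 1.06 ± 0.15, DGAT2 0.95 ± 0.13 and ACLY 0.77 ± 0.13, and FASN, ACACA and ELOVL6 were 0.49 ± 0.14, 0.47 ± 0.16 and 0.46 ± 0.14 higher, each in all 3 pairs. LPIN1 was at -0.16 ± 0.13, and SREBF1 and MLXIPL, which encode transcription factors of lipid synthesis, at 0.00 ± 0.13 and -0.16 ± 0.14. FADS2, ACSS2, AGPAT2 and PNPLA3 were at 0.04 ± 0.15, 0.03 ± 0.13, 0.00 ± 0.12 and -0.03 ± 0.15. The mean change of these 19 genes exceeded that of 13 adipocyte markers (the adipocyte list without THRSP) by 0.261 ± 0.177 (SD over 3 pairs), by 0.171, 0.147 and 0.464 in single pairs. The 19 genes were put together after members were seen to be higher, so this difference decides nothing, and more adipose tissue in the second samples stays open.

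Of 7 copies of the NBPF and NOTCH2NL families, which share near-identical sequence so that the values of single members are uncertain, 5 were higher in all 3 pairs and 0 passed in limma over all genes. NBPF14, NOTCH2NL, NBPF15 and NBPF1 had changes of 0.96 ± 0.14, 0.96 ± 0.13, 0.93 ± 0.13 and 0.91 ± 0.15 log2 units (SE, n = 3 pairs), NBPF8 0.60 ± 0.13, and NBPF4 and NBPF6 0.05 ± 0.14 and 0.03 ± 0.13.

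Macrophage genes outside the rule for named genes had changes of 1.61 ± 0.21 log2 units for GPNMB, 1.23 ± 0.24 for CD68, 1.21 ± 0.22 for LYZ, 1.13 ± 0.20 for VSIG4 and 0.75 ± 0.18 for CD163 (SE, n = 3 pairs), each higher in all 3 pairs. These were picked after their values were seen, and other members of the fixed macrophage list had smaller or negative changes: C1QB at 0.26 ± 0.14, AIF1 at 0.20 ± 0.13, MARCO at 0.13 ± 0.13, C1QA at 0.11 ± 0.13 and S100A8 at -0.16 ± 0.12. None of the genes of this paragraph passed in limma over all genes. The inducible macrophage genes TREM2 and SPP1 had changes of 0.07 ± 0.16 and 0.94 ± 0.60, and SPP1 was higher in 1 pair, by 3.06, and at -0.09 and -0.16 in the others.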
